A study of Mus musculus with 6 samples.

How the data were processed

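RNA sequencing was carried out on 6 libraries of hepatic stellate cells from livers of wild type C57BL/6 mice aged 35 weeks. Per the labels, the cells came from normal diet livers or from the tumour or the non-tumour region of high-fat diet livers, and each of these 3 sources was processed by perfusion at 37 or at 6 degrees. Per the labels' protocols, cells negative for CD31 and CD45.2 and positive for CD49a were sorted, RNA was extracted with Trizol, and libraries followed standard Illumina protocols. Each of the 6 groups held 1 library, and the labels give no replicate numbers. Nothing in the labels says whether the libraries came from separate animals or how many livers each one held. The p-values thus set effects only against the departures of these 6 libraries from additive effects of source and temperature. Those departures may be technical.

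The deposited values are FPKM (fragments per kilobase of transcript, scaled to the fragments mapped), listed by the authors for 24346 gene symbols in each library. Reads were aligned to mm10 with TopHat2 2.1.1 and Bowtie2 and quantified with Cuffdiff 2.2.1, per the submitters' processing notes, which list these tools without their settings. The annotation, the use of strand and the scaling inside Cuffdiff are not given in the sources used here. Without stated strand, an overlapping gene on the other strand could add to a value, and Cuffdiff can divide reads between near-identical copies, so values of Hspa1a, Hspa1b, the H2 genes, Hba-a1 and Serpina1a are uncertain in how they were divided. Entries that shared a symbol were summed.

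FPKM hold no counts, so depth was estimated from low values. Of 3639 genes with low values in at least 3 libraries, 1554 (42.7%) had values that were whole multiples of the smallest within 0.01 on the log2 scale, and the size of 1 step between libraries gave their relative depth. Scaled with 422 genes of a single annotated transcript, the libraries held about 1.87e+07 and 2.26e+07 fragments for normal diet (37 and 6 degrees), 1.63e+07 and 1.88e+07 for the non-tumour region and 1.61e+07 and 1.89e+07 for the tumour region. The estimate for the normal diet library of 37 degrees had quartiles of 1.58e+07 and 1.99e+07. At these depths 1 fragment on a transcript of 1 kb was worth 0.0443 to 0.0623 FPKM, and between 8330 and 9070 symbols were listed at 0 in a library.

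Genes were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. The pseudocount of 1 makes fold changes of genes with low values smaller than the ratio of their FPKM. Genes with a mean of at least 1 FPKM over the 6 libraries were kept, and 1291 symbols of small RNA genes were left out, which left 11556 genes. Most of these symbols were under the filter in any case, as 11614 genes were tested with small RNA genes kept. The linear model had liver source and temperature as additive terms, which leaves 2 residual degrees of freedom (5.37 with the empirical Bayes prior, fitted with an intensity trend). The residuals hold differences of the temperature effect between sources together with library noise. A temperature effect present in only some sources is thus counted partly as noise. The temperature effect was thus measured over 3 pairs of libraries and each source contrast over 2 pairs. P-values were adjusted by the Benjamini-Hochberg method and an adjusted p under 0.05 counted as passing. Errors beside log2 fold changes are standard errors from this model. The contrasts of the tumour and the non-tumour region with normal diet use the same normal diet libraries, so no overlap between them was counted.

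A total of 31 lists (20 of pathways or cell states and 11 of cell type markers) were written from general knowledge before the data were examined, as were the model, the named-gene rule and all alternatives other than the 6 described as added. Of these, 26 lists with at least 5 tested genes were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 26. Estimated correlations and fry were the alternatives. Camera compares a list with the other genes, whereas fry tests whether a list's genes move one way on balance and compares them with no other genes, so its counts answer another question. No list passed with an estimated correlation in any of the 4 contrasts; the smallest adjusted p was 0.508 for temperature, 0.351 for tumour region against normal diet, 0.505 for non-tumour region against normal diet and 0.337 for tumour against non-tumour region. All list calls in the text therefore rest on the preset correlation. Correlation between genes need not be the reason for every loss. The heat shock list had an estimated correlation of -0.00919, under the preset 0.01. Its unadjusted camera p for temperature still went from 5.10e-07 to 0.0325. With an estimated correlation, camera also draws on the 2 residual degrees of freedom, which leaves it little power here. The median, the mean and the camera direction of a list differed in sign in 10 tested results, 0 of them among those that passed. Some lists share genes, so their results are not separate. The NF-kB and secretory factor lists share Il1a, Il1b, Il6, Cxcl1, Ccl2 and Ccl20. The smooth muscle and myofibroblast lists share Acta2, Tagln and Cnn1. Hgf is a secretory factor and a quiescent stellate cell gene, and Timp1 a secretory factor and a myofibroblast gene.

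Named genes followed a fixed rule: for temperature, the 12 highest and the 12 lowest fold changes among passing genes with the same sign in all 3 pairs; for each source contrast, the 8 highest and 8 lowest, filled from genes that did not pass where needed. Predicted genes were skipped. Up to 4 members of each list, every passing member and a fixed set of stellate, stress and sort-marker genes could also be named. Pecam1, Ptprc and Itga1 encode CD31, CD45 and CD49a and were used for sorting, so they are given as checks of the sort and not as findings. The clock genes were chosen after their values were seen. Coordinates come from GENCODE vM21 on GRCm38, the assembly that mm10 denotes, in which 23268 symbols matched once.

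The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter or a mean of at least 5 FPKM, median-ratio rescaling, quantile normalization, small RNA genes kept, robust or untrended empirical Bayes, no source term, only the 4 libraries of the sources compared, and each pair left out. The additions made after seeing the data left out the tumour region library of 37 degrees (once per contrast), the endothelial and macrophage list genes, or the genes at least 2-fold higher at 6 degrees in all 3 pairs. The pipeline was tested on simulated data for the temperature contrast with 11556 genes and 100 seeded genes per size. It recovered 76% of genes changed by 1 log2 unit and 98% of those changed by 2, with 5 false genes among 179 called and 0 of the wrong sign. A seeded list reached an adjusted p of 1.34e-51 at the preset correlation and 0.0263 with an estimated correlation, and an unchanged list 0.604. Noise was drawn for each gene independently, and these p-values were adjusted over the seeded and the unchanged list alone. The simulation thus does not show how either setting behaves for correlated lists, such as the immediate early list (estimated correlation 0.745). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads were not used here.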

Results

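Hepatic stellate cells are the vitamin A-storing pericytes of the liver, which turn into matrix-producing myofibroblasts after injury. Their transcripts were measured by RNA sequencing after isolation at 37 or at 6 degrees from 3 kinds of liver tissue of mice aged 35 weeks: normal diet livers, the non-tumour region of high-fat diet livers and the tumour region of high-fat diet livers. Each of the 6 combinations had 1 library, with an estimated 1.61e+07 to 2.26e+07 fragments per library. Between 11056 and 11673 genes reached 1 FPKM in a library. With 1 library per group, values of single libraries carry no error of their own. Temperature was compared over 3 pairs of libraries and each pair of sources over 2.

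The first comparison addressed the side effects of warm incubation: which transcripts differed between cells isolated at 37 and at 6 degrees. Of the named genes that passed, 2 heat shock genes had the largest increases at 37 degrees. Hspa1a, which encodes an inducible HSP70 chaperone (GRCm38 chromosome 17, 34969190 to 34972156), rose by 4.37 ± 0.42 on the log2 scale (SE, 3 pairs, adjusted p = 0.0103). It was at 2.94, 4.01 and 5.85 FPKM at 6 degrees and at 167, 119 and 58.9 FPKM at 37 degrees in the normal diet, non-tumour and tumour libraries. Its near-identical neighbour Hspa1b (chromosome 17, 34956436 to 34959238) rose by 4.22 ± 0.67 (adjusted p = 0.0307). The co-chaperone gene Dnajb4 (chromosome 3, 152178511 to 152210302) rose by 1.10 ± 0.20 and Hsp90aa1, the inducible HSP90 (chromosome 12, 110690605 to 110702728), by 0.70 ± 0.12 (adjusted p = 0.044 and 0.042). Of the 17 heat shock list genes tested these 4 passed, against 8 when adjusted over the list alone. The list median was 0.42. Camera gave the heat shock list adjusted p = 2.21e-06, and adjusted p = 0.508 with an estimated correlation. In the same comparison the endothelial and macrophage list medians were -2.93 and -2.56. Of the 4 passing genes, 1, 0 and 2 passed without the normal diet, non-tumour and tumour pair, and Hspa1a had adjusted p = 0.0659 without the non-tumour pair. With a pseudocount of 0.1 FPKM Dnajb4 and Hsp90aa1 did not pass.

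Cebpb, Cebpd, Bhlhe40 and Hes1, which encode transcription factors, were among the other named genes that rose with temperature. Cebpb (chromosome 2, 167688915 to 167690418), a regulator of inflammatory and acute phase genes, rose by 1.22 ± 0.17 (adjusted p = 0.0211). Its relative Cebpd (chromosome 16, 15887286 to 15891031) rose by 1.38 ± 0.26 (adjusted p = 0.0486). Bhlhe40 (chromosome 6, 108660629 to 108666925), a repressor linked to hypoxia and the clock, rose by 1.88 ± 0.34 (adjusted p = 0.0436). The Notch target Hes1 (chromosome 16, 30064384 to 30067796) rose by 1.06 ± 0.11 (adjusted p = 0.0114). Kcne4, a potassium channel subunit (chromosome 1, 78816758 to 78820028), rose by 1.51 ± 0.09 (adjusted p = 0.00709). The nuclear long non-coding RNA Malat1 (chromosome 19, 5795690 to 5802672) rose by 1.09 ± 0.15 (adjusted p = 0.0197). The EGF family growth factor gene Ereg rose by 1.17 ± 0.21 and the small GTPase gene Rrad by 1.05 ± 0.16. Erdr1, which had no single match in the annotation, rose by 0.96 ± 0.11. Hes1 and Kcne4 passed without each of the 3 pairs. Cebpb, Cebpd and Bhlhe40 did not pass without the normal diet or the tumour pair, Malat1 and Erdr1 did not without the non-tumour pair, and Ereg and Rrad did not without any of the 3 (adjusted p from 0.0534 to 0.145). Cebpd, Bhlhe40 and Ereg also did not pass with a pseudocount of 0.1 FPKM.

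Immediate early genes, which cells switch on within minutes of a stimulus, had higher values at 37 degrees chiefly in normal diet and the tumour region, and of 30 list members tested Cebpb and Cebpd passed. Fos (chromosome 12, 85473890 to 85477273), a subunit of the AP-1 factor, was at 1548 against 99.7 FPKM in normal diet and 4114 against 265 FPKM in the tumour region, but at 429 against 236 FPKM in the non-tumour region. Its log2 fold change of 2.92 ± 0.63 did not pass (adjusted p = 0.0716). Egr1, a growth factor-responsive regulator (chromosome 18, 34859823 to 34864984), was at 561 against 59.2, 136 against 197 and 2078 against 205 FPKM in the normal diet, non-tumour and tumour libraries (adjusted p = 0.234). Jun had a log2 fold change of 1.86 (adjusted p = 0.0819) and Atf3 of 3.22 (adjusted p = 0.117). Without the non-tumour pair, Fos, Egr1, Jun and Atf3 passed (adjusted p = 0.00595, 0.00748, 0.0101 and 0.0466). The list median over 30 genes was 1.59 (camera, adjusted p = 1.36e-11, and adjusted p = 0.508 with an estimated correlation), with 2 genes passing over all genes tested and 21 adjusted over the list alone. The list medians of the single sources were 2.06 for normal diet, 0.32 for the non-tumour region and 2.87 for the tumour region; the difference between sources was not tested.

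**Figure D1:**
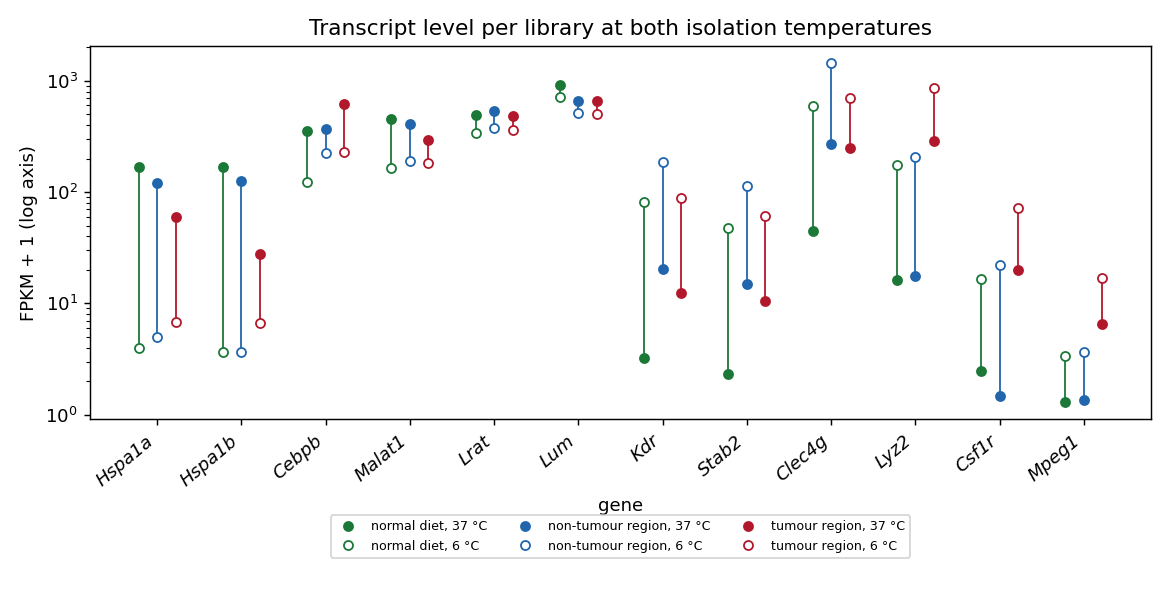
Levels of 12 genes in each library, as FPKM + 1 on a log axis, with filled points for 37 degrees, open points for 6 degrees, green for normal diet, blue for the non-tumour region and red for the tumour region, and lines joining the libraries of 1 source. Hspa1a lies between 58.9 and 167 FPKM at 37 degrees and between 2.94 and 5.85 FPKM at 6 degrees, whereas Kdr lies between 2.2 and 19.5 FPKM at 37 degrees and between 80.2 and 187 FPKM at 6 degrees.

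Inflammatory genes had higher values at 37 degrees chiefly in the tumour region, with NF-kB list medians of 0.08, 0.05 and 0.90 in the normal diet, non-tumour and tumour pairs; the difference between sources was not tested. The cytokine gene Il6 was at 1.01, 0.487 and 17.9 FPKM at 37 degrees and at 0.0883, 0.0528 and 0.263 FPKM at 6 degrees in the normal diet, non-tumour and tumour libraries (log2 fold change 1.76, adjusted p = 0.229). The chemokine gene Cxcl1 was at 137, 113 and 1288 against 21.7, 79.3 and 88.7 FPKM (adjusted p = 0.111). Without the non-tumour pair Cxcl1, Ccl2 and Ccl7 passed as higher by limma (adjusted p = 0.049, 0.049 and 0.0415). The cytokine gene Il1b went the other way without the tumour pair. There its log2 fold change was -1.68 (limma, adjusted p = 0.019). Of 23 NF-kB list genes, 10 were higher and 2 lower at 37 degrees in all 3 pairs. The list of NF-kB targets and inflammatory cytokines had a median of 0.32 over 23 genes (camera, adjusted p = 0.0375, and adjusted p = 0.649 with an estimated correlation). Of these, 0 passed by limma over all genes or adjusted over the list alone (8 higher and 2 lower at an unadjusted p under 0.05). This list's adjusted p was 0.676 without the tumour region pair, 0.104 under quantile normalization and 0.167 with a mean of at least 5 FPKM. Among 24 secreted factors of senescent cells, Ereg, the hepatocyte growth factor Hgf, the plasminogen activator Plat and the metalloproteinase inhibitor Timp1 rose and the macrophage elastase Mmp12 fell. Thus 4 were higher and 1 lower, against 9 and 3 adjusted over the list alone. Of these 5, 1, 0 and 0 passed without the normal diet, non-tumour and tumour pair, 2 under quantile normalization and 3 with a pseudocount of 0.1 FPKM. Camera gave the secretory factor list adjusted p = 0.00788, adjusted p = 0.508 with an estimated correlation and 0.064 without the tumour region pair. Of 11 inflammasome genes, Casp1, Casp8 and Il18, which process or carry inflammasome signals, fell (3 also adjusted over the list alone), and Casp1 fell by 1.14 ± 0.12 (adjusted p = 0.0119). Of these 3, 1, 0 and 2 passed without the normal diet, non-tumour and tumour pair, and Il18 did not under quantile normalization or with a pseudocount of 0.1 FPKM. Macrophage genes were lower in the same libraries, with a list median of -2.56. Camera gave the inflammasome list adjusted p = 0.0327, adjusted p = 0.540 with an estimated correlation and 0.126 without the non-tumour pair. Il33, an alarmin, had a log2 fold change of 0.24 (adjusted p = 0.475) and Gsdmd, the pore-forming executor of pyroptosis, of 0.15 (adjusted p = 0.303). The cell-cycle inhibitor Cdkn1a was at 152 FPKM in the tumour region library of 37 degrees and between 18.2 and 20 FPKM in the other 5 (adjusted p = 0.43), and Cdkn2b had a log2 fold change of -0.29 (adjusted p = 0.297). Cdkn2a was under the expression filter, at 0 to 0.323 FPKM.

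Genes of quiescent stellate cells were higher at 37 degrees by small amounts. Lrat (chromosome 3, 82892579 to 82903973), which esterifies vitamin A for storage, rose by 0.50 ± 0.07 (adjusted p = 0.0211), from 335, 373 and 361 to 494, 538 and 483 FPKM. Hgf rose by 0.41 ± 0.07, the stellate cell transcription factor Hand2 by 0.52 ± 0.09 and cytoglobin (Cygb) by 0.39 ± 0.07 (adjusted p = 0.0379, 0.0363 and 0.0423). Lrat, Hgf and Cygb did not pass under quantile normalization (adjusted p = 0.1, 0.0946 and 0.0758), and without the non-tumour pair Lrat, Hgf, Hand2 and Cygb did not (adjusted p = 0.126, 0.201, 0.193 and 0.171). None of the 4 passed without the normal diet pair, and Lrat was the 1 that passed without the tumour pair. These 4 of 24 list genes passed, against 18 adjusted over the list alone, and 22 of 24 were higher in all 3 pairs. Camera gave the quiescent stellate cell list (median 0.38) adjusted p = 3.89e-12, and adjusted p = 0.508 with an estimated correlation. Endothelial and macrophage markers moved the other way in these libraries, with list medians of -2.93 and -2.56. Of the other stellate cell genes, Des, Acta2 and Col1a1 had log2 fold changes of 0.29, -0.01 and -0.13 (adjusted p = 0.093, 0.974 and 0.709). Timp1 rose by 0.42 ± 0.06 and was the 1 myofibroblast gene of 25 to pass, also when adjusted over the list alone. Camera gave the myofibroblast list adjusted p = 0.00623, adjusted p = 0.508 with an estimated correlation, 0.0788 without the non-tumour pair and 0.104 under quantile normalization. The proteoglycan Lum rose by 0.36 ± 0.07 as the 1 passing gene of 20 collagens and matrix genes, but not under median-ratio rescaling (adjusted p = 0.0506). Timp1 and Lum did not pass under quantile normalization (adjusted p = 0.0624 and 0.225) or without any of the 3 pairs, and Lum did not with a pseudocount of 0.1 FPKM. The matrix list did not pass (camera, adjusted p = 0.0713) and without the tumour region pair reached 0.00108.

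Markers of liver sinusoidal endothelial cells, which line the sinusoid next to stellate cells, were far lower at 37 degrees. Kdr, the VEGF receptor 2 (chromosome 5, 75932827 to 75978458), fell by 3.56 ± 0.35 on the log2 scale (adjusted p = 0.0111), from 80.2, 187 and 86.6 FPKM at 6 degrees to 2.2, 19.5 and 11.5 FPKM at 37 degrees. The scavenger receptor gene Stab2 (chromosome 10, 86841198 to 87008025) fell by 3.27 ± 0.35 (adjusted p = 0.0115). The Fc receptor gene Fcgr2b (-3.63 ± 0.58), the lipase anchor Gpihbp1 (-3.59 ± 0.59), the DNase gene Dnase1l3 (-3.59 ± 0.49) and the lectin gene Clec4g (-2.55 ± 0.40) fell as well. Of 21 endothelial list genes 19 fell, and 21 adjusted over the list alone. The list medians were -3.78, -2.85 and -2.14 in the normal diet, non-tumour and tumour pairs. Camera gave the endothelial list adjusted p = 9.69e-22, and adjusted p = 0.508 with an estimated correlation. Pecam1, whose product CD31 was used to exclude cells, was at 0.9, 9.99 and 10.7 FPKM at 37 degrees and at 31.4, 90.6 and 53 FPKM at 6 degrees. Itga1, whose product CD49a was used to collect them, was at 87.6 to 204 FPKM in all 6. Of the 19 genes that fell, 2 passed without the non-tumour pair, where Kdr and Stab2 had adjusted p = 0.0588 and 0.0659, and all 19 passed without either of the other pairs. With a pseudocount of 0.1 FPKM 17 of the 19 passed.

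Macrophage markers were also lower at 37 degrees. Lyz2, lysozyme of myeloid cells (chromosome 10, 117277331 to 117282321), fell by 2.85 ± 0.39 (adjusted p = 0.0208), from 175, 204 and 857 to 15.4, 16.6 and 285 FPKM. Csf1r, the macrophage growth factor receptor (chromosome 18, 61100598 to 61132149), fell by 2.83 ± 0.37 (adjusted p = 0.0191). Mpeg1, a macrophage pore-forming protein (chromosome 19, 12460779 to 12465283), fell by 1.39 ± 0.12 (adjusted p = 0.00866). Of 17 macrophage and Kupffer cell genes tested 11 fell, and 16 adjusted over the list alone, with medians of -2.78, -3.54 and -1.38 in the 3 sources. Of these 11, 3, 0 and 11 passed without the normal diet, non-tumour and tumour pair, and 8 with a pseudocount of 0.1 FPKM. Camera gave the macrophage list adjusted p = 2.23e-13, and adjusted p = 0.508 with an estimated correlation. Ptprc, which encodes CD45, was at 0.397, 0.375 and 5.44 FPKM at 37 degrees and at 1.75, 2.73 and 16.5 FPKM at 6 degrees. The 5 neutrophil genes had a median of -0.84 with 0 passing by limma (3 lower at an unadjusted p under 0.05) and 2 lower adjusted over the list alone. Camera gave the neutrophil list adjusted p = 0.0140, adjusted p = 0.508 with an estimated correlation, 0.0668 without the non-tumour pair and 0.0948 under quantile normalization. Hepatocyte genes had medians of -2.60, -0.81 and 0.34 in the 3 sources (camera, adjusted p = 3.48e-04, adjusted p = 0.629 with an estimated correlation and 0.188 without the normal diet pair). Of 21 such genes 0 passed by limma over all genes or adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Alb, the albumin gene, was at 5.39, 6.01 and 26.6 FPKM at 37 degrees and at 29.3, 13.7 and 19.4 FPKM at 6 degrees.

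Proliferation genes were lower at 37 degrees, beside the endothelial and macrophage markers. Cdc20, an activator of the anaphase-promoting complex (chromosome 4, 118432901 to 118437352), fell by 1.33 ± 0.24 (adjusted p = 0.0442). The mitotic cyclin gene Ccnb1 (chromosome 13, 100778650 to 100786570) fell by 0.96 ± 0.14 (adjusted p = 0.0254). Of 24 such genes 7 fell, and 18 adjusted over the list alone, with medians of -0.35, -0.98 and -1.14 in the 3 sources. The 7 became 7, 0 and 2 without the normal diet, non-tumour and tumour pair, with Cdc20 and Ccnb1 lost without either of the last 2, and 5 passed with a pseudocount of 0.1 FPKM, Cdc20 not among them. Camera gave the proliferation list adjusted p = 1.68e-10, and adjusted p = 0.508 with an estimated correlation. The cold-inducible RNA-binding protein genes Cirbp and Rbm3 had log2 fold changes of -0.11 and 0.12 (adjusted p = 0.668 and 0.575). The metallothionein genes Mt1 and Mt2, which bind zinc, had log2 fold changes of 1.16 and 1.24 (adjusted p = 0.0883 and 0.0693). The ribosomal protein list had a median of 0.08 with 0 of 25 genes passing by limma or adjusted over the list alone (1 higher unadjusted). Camera gave the ribosomal list adjusted p = 0.00567, and adjusted p = 0.649 with an estimated correlation. Its median was -0.032 under quantile normalization (adjusted p = 0.0948), and its adjusted p was 0.0613 without the normal diet pair and 0.0851 without the tumour pair.

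**Figure D2:**
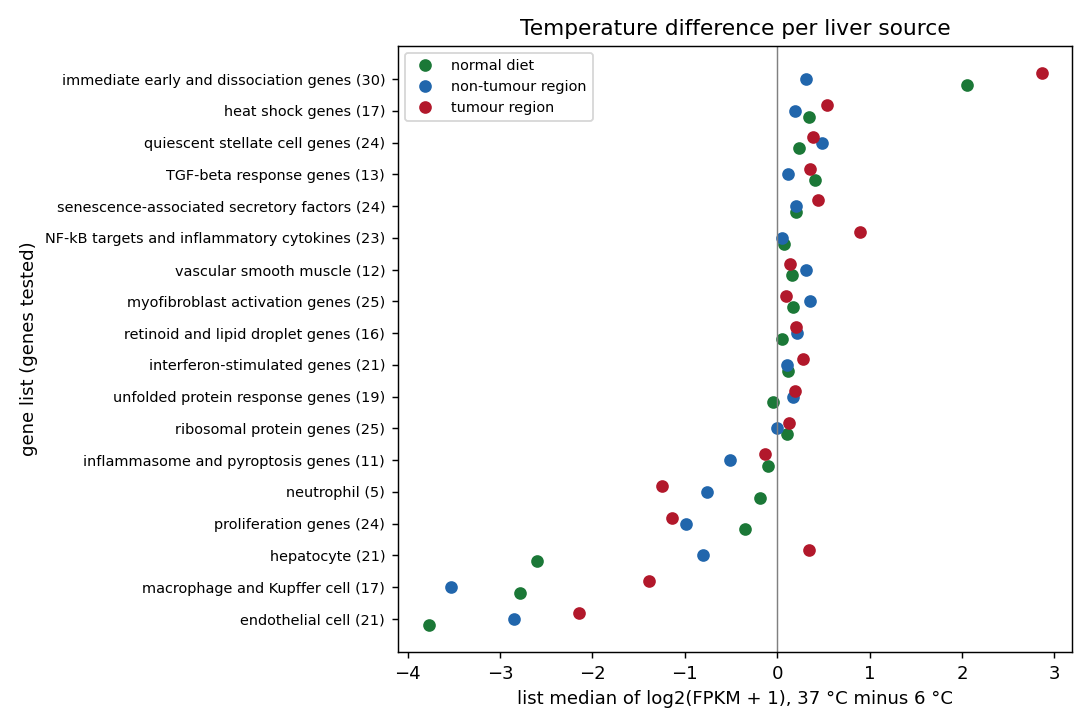
Median difference in log2(FPKM + 1) between 37 and 6 degrees of the genes of each of the 18 lists that passed, with the number of genes tested in brackets and 1 point per liver source. Endothelial medians run from -3.78 to -2.14 and immediate early medians from 0.32 to 2.87; the ribosomal list, whose direction reverses under quantile normalization, lies near 0.

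By limma, 593 of 11556 genes differed with temperature (59 higher and 534 lower at 37 degrees), of which 11 higher and 407 lower genes differed at least 2-fold, and all 593 had the same sign in all 3 pairs. The count was 330 with a mean of at least 5 FPKM, 82 without the non-tumour pair and 0 without the low-value filter (1019 higher and 1820 lower at an unadjusted p under 0.05) or without the source term (424 higher and 814 lower). Of 78 named genes that passed, 67 did so under quantile normalization, 59 with a pseudocount of 0.1 FPKM and 0 without the source term. Without the normal diet, non-tumour and tumour pair 48, 7 and 50 of them passed, and Kcne4, Hes1, Tek and Gpr182 passed without each of the 3 pairs. Of the 18 lists that passed camera, 8 did not without the source term (adjusted p from 0.129 to 0.199): the NF-kB, inflammasome, secretory factor, myofibroblast, neutrophil, retinoid, unfolded protein response and vascular smooth muscle lists.

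The second comparison asked how stellate cells of the tumour region differed from those of normal diet livers. Myofibroblast and vascular smooth muscle genes were higher in the tumour region, beside macrophage genes (list median 2.63). Acta2 (chromosome 19, 34241090 to 34255590), smooth muscle actin and the usual marker of activated stellate cells, rose by 1.44 ± 0.17 on the log2 scale (SE, 2 pairs, adjusted p = 0.0126), changing from 107 and 112 FPKM to 266 and 337 FPKM at 37 and 6 degrees. The actin-binding gene Tagln (chromosome 9, 45929619 to 45936058) rose by 1.59 ± 0.16 (adjusted p = 0.00881). The calponin gene Cnn1 (chromosome 9, 22099216 to 22109630) rose by 2.05 ± 0.19 (adjusted p = 0.00792) and fibronectin (Fn1) by 1.84 ± 0.16 (adjusted p = 0.00716). Mmp2, a gelatinase, fell by 1.38 ± 0.10 (adjusted p = 0.00693), as did Loxl1 and Cthrc1, which act on elastin and collagen matrix. Of 25 myofibroblast genes 13 rose and 3 fell (16 and 4 adjusted over the list alone), and 12 of these 16 passed under quantile normalization. Camera gave the myofibroblast list adjusted p = 6.94e-05, and adjusted p = 0.351 with an estimated correlation. Of 20 collagens and matrix genes 7 rose, among them the basement membrane collagens Col4a1 and Col4a2, and Lum fell, with the same counts adjusted over the list alone. Under quantile normalization 5 of these 7, Col4a1, Col4a2, Col14a1, Col5a1 and Sparc, did not pass (adjusted p = 0.145, 0.0934, 0.0879, 0.0632 and 0.158). Camera gave the matrix list adjusted p = 0.00862, adjusted p = 0.641 with an estimated correlation and 0.108 under quantile normalization. Col1a1, the main fibrillar collagen chain, had a log2 fold change of 0.01 (adjusted p = 0.976). Of 12 vascular smooth muscle genes 6 rose, and 9 adjusted over the list alone. Acta2, Tagln and Cnn1 belong to this list and to the myofibroblast list, so the calls of these lists are partly the same. Camera gave the smooth muscle list adjusted p = 5.35e-06, and adjusted p = 0.351 with an estimated correlation.

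Macrophage genes had the highest list median of the 26 tested in this comparison. Of the named genes that passed, Ccl4, Cd74, H2-Aa and H2-Ab1 had the 4 largest increases. Cd74, the invariant chain of MHC class II (chromosome 18, 60803848 to 60812652), rose by 4.33 ± 0.65 (adjusted p = 0.0199), from 15.2 and 113 FPKM in normal diet to 621 and 1205 FPKM in the tumour region at 37 and 6 degrees. Genes of class II chains, H2-Aa (chromosome 17, 34282744 to 34287823) and H2-Ab1 (chromosome 17, 34257689 to 34269419) rose by 4.31 ± 0.49 and 4.31 ± 0.54 (adjusted p = 0.0108 and 0.0134). The chemokine gene Ccl4 (chromosome 11, 83662584 to 83664683) rose by 4.43 ± 0.67 (adjusted p = 0.0199). Ly6c1, a surface protein of endothelial cells and of myeloid cells (chromosome 15, 75044018 to 75048830), rose by 4.01 ± 0.45, the fatty acid carrier Fabp4 by 4.02 ± 0.81 and the Fc receptor chain Fcer1g by 3.71 ± 0.57. Of 17 macrophage genes 10 rose (16 higher and 1 lower adjusted over the list alone), with list medians of 3.16 at 37 degrees and 2.12 at 6 degrees. Camera gave the macrophage list adjusted p = 8.39e-09, and adjusted p = 0.399 with an estimated correlation. Ptprc was at 0.397 and 1.75 FPKM in normal diet and at 5.44 and 16.5 FPKM in the tumour region. Of 5 neutrophil genes Csf3r, Il1r2 and S100a9 rose, so 3 passed, against 4 adjusted over the list alone. Csf3r did not pass under quantile normalization (adjusted p = 0.107). Camera gave the neutrophil list adjusted p = 0.00188, and adjusted p = 0.351 with an estimated correlation. Of 21 endothelial genes 4 rose, and 8 adjusted over the list alone, with list medians of 1.96 at 37 degrees and 0.36 at 6 degrees. Camera gave the endothelial list adjusted p = 2.25e-06, and adjusted p = 0.455 with an estimated correlation.

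Genes of the NF-kB, secretory factor and unfolded protein response lists were higher in the same tumour libraries, beside the macrophage markers. The chemokine genes Cxcl2 (chromosome 5, 90903871 to 90905938) and Ccl2 (chromosome 11, 82035571 to 82037453), which attract neutrophils and monocytes, rose by 2.57 ± 0.18 and 2.02 ± 0.22 (adjusted p = 0.00693 and 0.0103). The adhesion molecule gene Icam1 rose by 1.16 ± 0.23 (adjusted p = 0.0393). Of 23 NF-kB targets 9 rose, and 17 adjusted over the list alone. Camera gave the NF-kB list (medians 1.99 at 37 degrees and 0.70 at 6 degrees) adjusted p = 1.96e-09, and adjusted p = 0.351 with an estimated correlation. Of 24 senescence-associated secretory factors 10 rose and 1 fell (15 and 3 adjusted over the list alone). Camera gave the secretory factor list adjusted p = 8.59e-07, and adjusted p = 0.351 with an estimated correlation. The stress cytokine Gdf15 (2.04 ± 0.22) and Igfbp3, a carrier of insulin-like growth factors (2.06 ± 0.16), were among those that rose. Cdkn1a had a log2 fold change of 1.47 that did not pass (adjusted p = 0.28). Hspa5, the chaperone BiP of the endoplasmic reticulum (chromosome 2, 34771970 to 34777547), rose by 1.16 ± 0.17 (adjusted p = 0.0187). Of 19 unfolded protein response genes 6 rose, and 9 adjusted over the list alone. Of these 6, Calr, Pdia6 and Sdf2l1 did not pass under quantile normalization (adjusted p = 0.0521, 0.198 and 0.0597). Camera gave the unfolded protein response list adjusted p = 2.25e-06, and adjusted p = 0.392 with an estimated correlation. Of 21 interferon-stimulated genes 5 rose, and 9 adjusted over the list alone. Camera gave the interferon list adjusted p = 2.40e-06, and adjusted p = 0.351 with an estimated correlation. Of 19 glycolysis and hypoxia genes 5 rose, and 11 adjusted over the list alone. Camera gave the glycolysis list adjusted p = 1.71e-05, and adjusted p = 0.351 with an estimated correlation. Among 12 MHC class I genes B2m, H2-K1 and H2-T23 rose, so 3 passed, against 8 adjusted over the list alone. Camera gave the MHC class I list adjusted p = 1.96e-04, adjusted p = 0.351 with an estimated correlation and 0.0753 under quantile normalization. H2-K1 had a log2 fold change of 0.52 ± 0.10 here and of -0.09 under quantile normalization (adjusted p = 0.573), where B2m did not pass either (adjusted p = 0.208).

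Proliferation genes and the enzyme genes Cyp2e1 and Inmt were lower in the tumour region, in libraries where macrophage and endothelial genes were higher (list medians 2.63 and 1.18). Cyp2e1, an ethanol-inducible cytochrome P450 (chromosome 7, 140763739 to 140774987), fell by 3.19 ± 0.21 (adjusted p = 0.00693), from 39.4 and 48.7 to 4.34 and 3.53 FPKM. The methyltransferase gene Inmt (chromosome 6, 55170626 to 55175043) fell by 2.92 ± 0.24 and the ficolin gene Fcna (chromosome 2, 25624666 to 25628030), a lectin of innate immunity, fell by 2.43 ± 0.21 (adjusted p = 0.00716 for both). Lcn8, Igsf21, Ackr4 and Cox8b also fell, with log2 fold changes of -2.92, -2.76, -2.46 and -2.45. Ass1, a urea cycle enzyme, was at 9.76 and 9.99 FPKM in normal diet and at 0 and 1.82 FPKM in the tumour region. Ccnb1 fell by 2.13 ± 0.18 and Cdc20 fell by 2.30 ± 0.29 (adjusted p = 0.00716 and 0.0143). Of 24 proliferation genes 21 fell, and 23 adjusted over the list alone. Camera gave the proliferation list (median -1.72) adjusted p = 6.89e-18, and adjusted p = 0.351 with an estimated correlation. Cyp2e1 and Ass1 are members of the hepatocyte marker list. Of 21 hepatocyte genes 3 were lower by limma, and 4 adjusted over the list alone. Hepatocyte genes had list medians of 1.17 at 37 degrees and -1.52 at 6 degrees. Camera gave the hepatocyte list adjusted p = 0.0715. Cirbp fell by 1.06 ± 0.16 and Rbm3 fell by 0.63 ± 0.13. The ribosomal protein list had a median of 0.13 (camera, adjusted p = 0.00593, and adjusted p = 0.641 with an estimated correlation), which became -0.107 under quantile normalization (adjusted p = 0.0488). Of its 25 genes 0 passed by limma or adjusted over the list alone (2 higher unadjusted). Quiescent stellate cell genes went both ways, with the collectins Colec10 and Colec11 among 5 that rose and Hand2 and Hgf among 4 that fell. Camera gave the quiescent stellate cell list (median 0.03) adjusted p = 0.912.

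By limma, 702 genes were higher and 380 lower in the tumour region than in normal diet, 416 and 200 of them by at least 2-fold. The total of 1082 was 681 with a mean of at least 5 FPKM, 657 with the 4 libraries of these sources alone and 505 without the low-value filter. Under quantile normalization the split was 541 higher and 471 lower, and 124 of the 147 named genes that passed did so there. Of the passing list genes, 8 of 9 NF-kB, 3 of 4 endothelial, 5 of 6 vascular smooth muscle, 4 of 5 interferon and 8 of 9 quiescent genes passed there. With a pseudocount of 0.1 FPKM 115 named genes did, among them 4 of the 10 macrophage, 1 of the 4 endothelial, 6 of the 9 NF-kB, 16 of the 21 proliferation, 4 of the 5 interferon and 7 of the 9 quiescent genes, and Ccl4, Fabp4, Cthrc1, Hgf, Col4a1 and Rbm3 did not. The total was also 505 without the tumour region library of 37 degrees, where the lone tumour library is assumed to vary like the other groups. Across genes, which are not independent replicates, the fold changes at 37 and at 6 degrees correlated with Pearson r = 0.652 and Spearman rho = 0.533, and 67.5% of genes had the same sign.

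The third comparison set the non-tumour region of high-fat diet livers against normal diet, which concerns the diet and the region without tumour. Proliferation genes had the lowest list median of the 26 tested, -2.44, and endothelial genes had one of 1.86. Cdca3, which promotes mitotic entry (chromosome 6, 124829547 to 124833701), fell by 3.29 ± 0.21 (adjusted p = 0.00624), from 16.5 and 25.6 to 0.501 and 2.24 FPKM at 37 and 6 degrees. The spindle gene Prc1 fell by 3.16 ± 0.23 and Rrm2, a ribonucleotide reductase subunit (chromosome 12, 24708241 to 24714146), fell by 3.01 ± 0.24 (adjusted p = 0.00653 and 0.00698). Of 24 proliferation genes 20 fell, and 24 adjusted over the list alone. Camera gave the proliferation list (medians -2.77 at 37 degrees and -2.14 at 6 degrees) adjusted p = 2.51e-26, and adjusted p = 0.505 with an estimated correlation. Spp1, the secreted matrix protein osteopontin (chromosome 5, 104435118 to 104441050), fell by 3.18 ± 0.23 (adjusted p = 0.00653). Cyp2e1 (-2.87 ± 0.21), Inmt (-3.14 ± 0.24), Cthrc1 (-3.11 ± 0.35) and Lcn8 (-3.02 ± 0.36) fell as well. Ass1 was at 9.76 and 9.99 FPKM in normal diet and at 0 and 0.601 FPKM in the non-tumour region.

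Endothelial and unfolded protein response genes stood higher in the non-tumour region. Zbtb8b, a zinc finger gene (chromosome 4, 129425765 to 129440853), rose by 3.16 ± 0.26 (adjusted p = 0.00698) and Clca3a1 (chromosome 3, 144729677 to 144760977) by 2.58 ± 0.08 (adjusted p = 0.00248), from 53.1 and 45.2 to 322 and 275 FPKM. Cd36, a fatty acid transporter (chromosome 5, 17781690 to 17888801), rose by 3.27 ± 0.45 (adjusted p = 0.0193). The hyaluronan receptor gene Lyve1 (chromosome 7, 110850607 to 110863239) rose, with 0.136 and 24.4 FPKM in normal diet and 15.1 and 115 FPKM in the non-tumour region (adjusted p = 0.0433). The adhesion genes Selp and Jam2 rose by 2.79 ± 0.40 and 2.59 ± 0.24, the endothelial proteoglycan Esm1 by 2.56 ± 0.16 and Olfm2 by 2.71 ± 0.18. Of 21 endothelial genes 6 rose, and 21 adjusted over the list alone, with medians of 2.42 at 37 degrees and 1.26 at 6 degrees. Of these 6, Lyve1 and Ptprb did not pass with a pseudocount of 0.1 FPKM and Vwf did not under quantile normalization (adjusted p = 0.054). Camera gave the endothelial list adjusted p = 7.50e-12, and adjusted p = 0.505 with an estimated correlation. Hspa5 rose by 1.04 ± 0.17 (adjusted p = 0.032). Of 19 unfolded protein response genes 7 rose, and 12 adjusted over the list alone. Camera gave the unfolded protein response list adjusted p = 2.03e-06, and adjusted p = 0.505 with an estimated correlation. Irf7 and Oas2 rose among 21 interferon-stimulated genes, so 2 passed, and 10 adjusted over the list alone. Camera gave the interferon list adjusted p = 2.03e-06, and adjusted p = 0.505 with an estimated correlation. Of 12 MHC class I genes 4 rose, and 9 adjusted over the list alone. Of these 4, H2-D1, H2-K1 and Tapbp did not pass under quantile normalization (adjusted p = 0.439, 0.354 and 0.0839). Camera gave the MHC class I list adjusted p = 2.03e-06, and adjusted p = 0.505 with an estimated correlation. Of 19 glycolysis and hypoxia genes 6 rose, and 10 adjusted over the list alone. Camera gave the glycolysis list adjusted p = 1.38e-04, and adjusted p = 0.505 with an estimated correlation. Of 23 NF-kB targets 3 rose, and 5 adjusted over the list alone. Camera gave the NF-kB list adjusted p = 1.06e-04, and adjusted p = 0.700 with an estimated correlation. The collectin gene Colec11 (chromosome 12, 28594173 to 28623377) rose by 1.06 ± 0.14 and Igfbp3 (chromosome 11, 7206086 to 7213923) by 1.90 ± 0.16.

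Hepatocyte genes had a list median of -0.77 in this comparison. Of 21 hepatocyte genes Ass1, Cyp2e1 and Trf passed as lower, also adjusted over the list alone, with list medians of 0.08 at 37 degrees and -1.42 at 6 degrees. Camera gave the hepatocyte list adjusted p = 4.44e-04, and adjusted p = 0.793 with an estimated correlation. The oxidative phosphorylation list had a median of -0.11 with 0 of 22 genes passing by limma or adjusted over the list alone (4 lower unadjusted). Camera gave the oxidative phosphorylation list adjusted p = 0.0244, and adjusted p = 0.505 with an estimated correlation. Of 17 NRF2 genes Nqo1, a quinone reductase, fell by 0.96 ± 0.16 as the 1 to pass, also adjusted over the list alone. Camera gave the NRF2 list adjusted p = 0.0392, and adjusted p = 0.505 with an estimated correlation. Macrophage genes had a list median of -0.04. Camera gave the macrophage list adjusted p = 0.617. Of 25 myofibroblast genes 7 rose, Fn1 and Tagln among them, and 4 fell (7 higher and 7 lower adjusted over the list alone). Of these 11, Tagln, Postn and Thbs1 did not pass under quantile normalization (adjusted p = 0.0868, 0.0542 and 0.057). Camera gave the myofibroblast list adjusted p = 0.977. Acta2 had a log2 fold change of -0.03 (adjusted p = 0.953) and Col1a1 of -0.84 (adjusted p = 0.0908). Immediate early genes had list medians of -0.99 at 37 degrees and 0.84 at 6 degrees. Camera gave the immediate early list adjusted p = 0.925.

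By limma, 344 genes were higher and 299 lower in the non-tumour region than in normal diet, 172 and 220 of them by at least 2-fold, and the total of 643 was 268 without the low-value filter. Under quantile normalization the split was 303 higher and 346 lower, and 82 of the 94 named genes that passed did so there. The 12 that did not were H2-D1, H2-K1, Tapbp, Tagln, Postn, Thbs1, Vwf, Cenpe, Ldha, Pdia6, Rdh10 and Steap4. With a pseudocount of 0.1 FPKM 86 did, and the 8 that did not were Lyve1, Ptprb, Ass1, Cenpe, Tyms, Hyou1, Rdh10 and Thbs1. Across genes, which are not independent replicates, the fold changes at 37 and at 6 degrees correlated with Pearson r = 0.645 and Spearman rho = 0.510, with the same sign in 66.7% of genes.

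The fourth comparison, of the tumour with the non-tumour region of high-fat diet livers, asked what distinguished cells of the tumour-bearing part. Macrophage genes had the highest list median of the 26 tested, 2.72. Ms4a7, a macrophage membrane protein (chromosome 19, 11321039 to 11336146), rose by 2.96 ± 0.20 (adjusted p = 0.0383) and Mpeg1 by 2.23 ± 0.15 (adjusted p = 0.0383). The chemokine gene Ccl3 (chromosome 11, 83647844 to 83649355) rose by 2.90 ± 0.29 (adjusted p = 0.041), the lectin gene Clec4a3 by 2.75 ± 0.31, Pld4 by 2.66 ± 0.26, Laptm5 by 2.65 ± 0.26 and the phosphatase gene Ptpn6 by 2.53 ± 0.20. Of 17 macrophage list genes 2 rose, Mpeg1 and the Fc receptor gene Fcgr1, and 16 adjusted over the list alone. The list had medians of 3.74 at 37 degrees and 1.71 at 6 degrees. Camera gave the macrophage list adjusted p = 1.56e-19, and adjusted p = 0.337 with an estimated correlation. Cd74, Ccl4 and Lyz2 had log2 fold changes of 3.87, 4.19 and 3.04 that did not pass (adjusted p = 0.102, 0.0873 and 0.0845). All 5 neutrophil genes passed adjusted over the list alone, and 0 did by limma over all genes (5 higher at an unadjusted p under 0.05). Camera gave the neutrophil list (median 1.24) adjusted p = 1.57e-05, and adjusted p = 0.337 with an estimated correlation.

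Beside these markers, genes of the myofibroblast and secretory factor lists were higher in the tumour region. Gdf15 (chromosome 8, 70629393 to 70632456) rose by 2.60 ± 0.22 (adjusted p = 0.0383), from 1.28 and 0.742 to 16.8 and 7.24 FPKM at 37 and 6 degrees. Wisp2, a secreted matricellular protein with no single match in the annotation, rose by 2.56 ± 0.25 (adjusted p = 0.039). The calcium-binding gene S100a6 (chromosome 3, 90612882 to 90624181) rose by 1.87 ± 0.17 (adjusted p = 0.0383), and Cnn1 by 1.83 ± 0.19 and Spp1 by 2.16 ± 0.23 (adjusted p = 0.0429 for both). Acta2 had a log2 fold change of 1.47 ± 0.17 that did not pass (adjusted p = 0.0546). S100a6, Cnn1 and Spp1 were the 3 of 25 myofibroblast genes to pass, and 15 passed adjusted over the list alone, with list medians of 0.50 at 37 degrees and 0.58 at 6 degrees. Camera gave the myofibroblast list adjusted p = 9.18e-14, and adjusted p = 0.337 with an estimated correlation. Cnn1 was also the 1 passing gene of 12 vascular smooth muscle genes, and 5 passed adjusted over the list alone. Camera gave the smooth muscle list adjusted p = 1.01e-05, and adjusted p = 0.337 with an estimated correlation. Of 24 secretory factors Gdf15 and the proteinases Mmp12 (2.46 ± 0.26) and Mmp13 (2.29 ± 0.24) rose, so 3 passed, and 8 adjusted over the list alone. The secretory factor list medians were 0.97 at 37 degrees and 0.32 at 6 degrees. Camera gave the secretory factor list adjusted p = 1.11e-09, and adjusted p = 0.337 with an estimated correlation. Of 23 NF-kB targets Ccl3 and Cxcl2 rose, so 2 passed, and 5 adjusted over the list alone. The NF-kB list medians were 0.96 at 37 degrees and 0.05 at 6 degrees, so the difference lay chiefly in the libraries of 37 degrees. Camera gave the NF-kB list adjusted p = 2.03e-06, and adjusted p = 0.418 with an estimated correlation. The quiescent stellate cell list had a median of -0.12 with 0 of 24 genes passing by limma over all genes or adjusted over the list alone (2 lower unadjusted). Camera gave the quiescent stellate cell list adjusted p = 4.48e-04, and adjusted p = 0.418 with an estimated correlation. Lrat had a log2 fold change of -0.10 (adjusted p = 0.706). Under quantile normalization Cnn1, Spp1, Mmp12, Mmp13, Clec4a3 and Fcgr1 did not pass, with adjusted p from 0.0541 to 0.0809, whereas Acta2 passed under median-ratio rescaling (adjusted p = 0.0496).

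Some lists differed between the tumour and the non-tumour region at 1 temperature more than at the other. Immediate early genes had list medians of 2.46 at 37 degrees and -0.02 at 6 degrees, with 0 of 30 genes passing by limma over all genes (4 higher unadjusted) and 1 adjusted over the list alone. Camera gave the immediate early list adjusted p = 6.12e-10, and adjusted p = 0.418 with an estimated correlation. Fos had differences of 3.26 and 0.17 and Egr1 of 3.92 and 0.06 at 37 and 6 degrees. Proliferation genes were instead higher at both temperatures, with list medians of 0.55 at 37 degrees and 0.83 at 6 degrees. Their list median over both was 0.62, with 0 of 24 passing by limma (14 higher unadjusted) and 9 adjusted over the list alone. Camera gave the proliferation list adjusted p = 3.93e-09, and adjusted p = 0.418 with an estimated correlation. Endothelial genes had list medians of -0.19 at 37 degrees and -0.89 at 6 degrees, with 0 of 21 passing by limma (4 lower unadjusted) and 1 lower adjusted over the list alone. Camera gave the endothelial list adjusted p = 1.01e-05, and adjusted p = 0.418 with an estimated correlation. Kdr had a log2 fold change of -0.91 (adjusted p = 0.551). The differences between temperatures were not tested, since each cell of the design holds 1 library.

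**Figure D3:**
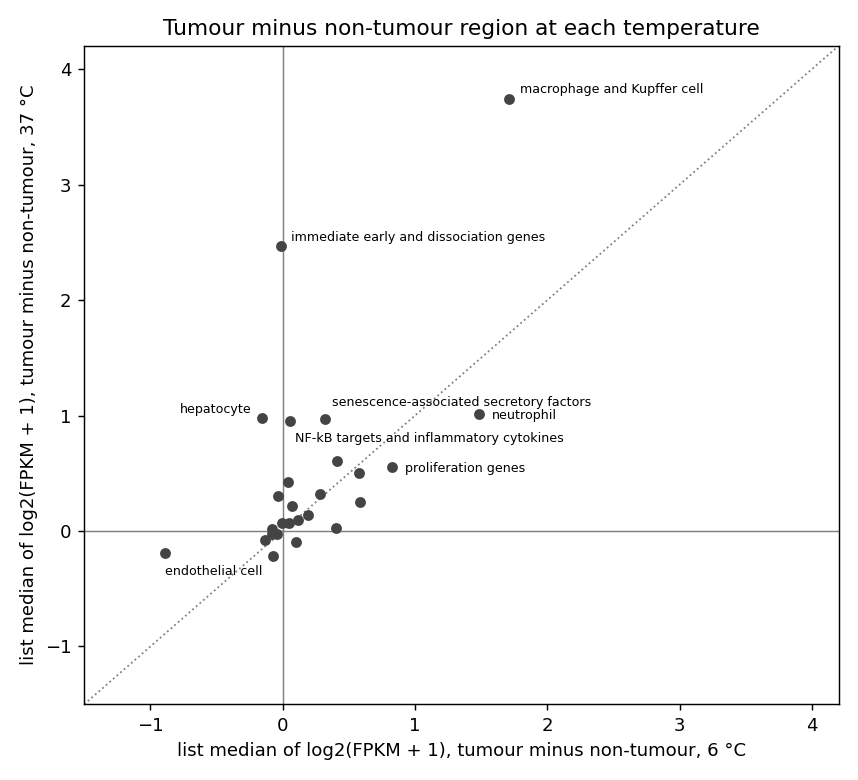
Median difference in log2(FPKM + 1) between the tumour and the non-tumour region for each of the 26 tested lists, at 6 degrees on the x axis and at 37 degrees on the y axis, with a dotted line of equal values. Macrophage genes lie at 1.71 and 3.74, whereas immediate early genes lie at -0.02 at 6 degrees and 2.46 at 37 degrees, far above the line.

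By limma, 52 genes were higher and 0 lower in the tumour than in the non-tumour region (736 higher and 434 lower at an unadjusted p under 0.05), and the smallest adjusted p was 0.0383. Under quantile normalization 36 genes were higher and 0 lower, and at an unadjusted p under 0.05 the split was 590 higher and 594 lower. The count was 0 with a pseudocount of 0.1 FPKM, without the low-value filter, with a mean of at least 5 FPKM and with the 4 libraries of these sources alone. It was 0 without the tumour region library of 37 degrees (580 higher and 328 lower unadjusted), 1 lower gene with small RNA genes kept, and 122 with robust empirical Bayes. Of the 52 genes, 30 were also at least 2-fold higher at 6 than at 37 degrees in all 3 sources. Across genes, which are not independent replicates, the fold changes at the 2 temperatures correlated with Pearson r = 0.481 and Spearman rho = 0.278, and 59.1% had the same sign.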

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

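The tests of scaling and of other splits of the libraries were chosen beforehand; all other tests of explanations in this part were chosen only after the result was seen.

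Endothelial and macrophage markers stood higher in the libraries of 6 degrees in all 3 sources, with list medians of 2.14 or more for endothelial genes on the log2 scale, and Clec4g reached 1446 FPKM and Lyz2 857 FPKM. A lower share of stellate cells that raises every other type alike is argued against in the non-tumour and tumour pairs. There the hepatocyte median lay 2.04 and 2.48 above the endothelial one (sums of their median absolute deviations 1.02 and 0.475). These deviations are across genes. Each pair holds 1 library per temperature, so they give no error of the difference between libraries. The hepatocyte list is limited by low values, which shrink fold changes, as 14 of its 23 genes reached 1 FPKM in every library. A lower share of stellate cells as such stays open, since 22 of 24 quiescent stellate cell genes were lower at 6 degrees in all 3 pairs. The value of 1 fragment differed within pairs by at most 0.271. FPKM are already scaled to the fragments mapped, so this was no separate test of depth. In the normal diet pair a lower share that raises every other type alike cannot be told apart from the other explanations. The hepatocyte, macrophage and endothelial medians were all low there, at -2.60, -2.78 and -3.78, and the hepatocyte one lay 1.18 above the endothelial one (sum 1.82). More endothelial cells and more macrophages after cold isolation stay open as candidate explanations. The FPKM added at 6 degrees kept nearly the same order of genes in every source (lowest Spearman rho 0.935 for the endothelial and 0.931 for the macrophage list). The sort against CD31 and CD45.2 was meant to remove both types. Pecam1 and Ptprc, which encode CD31 and CD45, still had transcripts at 6 degrees, above those at 37 degrees in each source. A like loss of every such transcript at 37 degrees would give the same rho. A direct effect of temperature on these genes, or on the surface proteins used for sorting, is thus also open. Of 21 endothelial genes 14 and of 18 macrophage genes 12 reached 1 FPKM in the normal diet library of 37 degrees, and 0 of either are in another list. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real split (593, the real one itself, highest other 0). With 10 splits the share cannot fall under 0.1. Of these splits 4 put 1 library of each source on either side, as the real one does, and the other 3 of them gave 0 genes. With 4 splits the share cannot fall under 0.25. In the other splits a temperature difference counts as residual spread, which would lower their counts. Their counts of 0 are thus no measure of what arises without such a difference.

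Immediate early genes stood higher in the libraries of 37 degrees. Scaling is argued against, since the lower of the list medians under quantile normalization and median-ratio rescaling was 1.57. A larger share of endothelial cells or macrophages at 37 degrees is argued against too, since the highest of their list medians over the 3 pairs was -1.38. Higher levels of these transcripts inside the endothelial cells or macrophages that remained were not tested and stay open. Cells of another type cannot be told apart from the temperature, since the highest of the other cell type medians over the 3 pairs was 0.340, of hepatocyte genes in the tumour pair, and vascular smooth muscle medians were 0.142 to 0.313. The immediate early medians of the 3 sources spanned 2.55, and with 1 preparation per source and temperature, handling of a single preparation cannot be told apart from the temperature. The effect of warm digestion itself is the biological explanation the design names, and it stays open as a hypothesis that repeated preparations would test.

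Macrophage genes stood higher in the tumour than in the non-tumour region, with Cd74 at 621 and 1205 FPKM and C1qb at 216 and 424 FPKM in the tumour libraries of 37 and 6 degrees. A lower share of stellate cells that raises other types alike is argued against, since the higher of the endothelial medians was -0.191 while the lower macrophage median was 1.71. More macrophages among the sorted cells of the tumour region stays open, although the sort against CD45.2 was meant to remove them. The FPKM added in the tumour library kept nearly the same order of genes at both temperatures (Spearman rho 0.980). This cannot decide the question, since any like rise of these genes would keep their order. Expression of these genes by stellate cells of the tumour region would give the same rho and stays open, untested.

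Among the named genes, 10 had effects of at least 2-fold in opposite directions in different libraries, and 6 list medians had opposite signs at least 1 log2 unit apart. None of these differences was tested, since each rests on single libraries. Opposite signs of any size were more frequent, at 105 of 352 named genes for temperature. For the non-tumour region against normal diet, the effect at 6 degrees lay above that at 37 degrees by 3.34 for Atf3, 3.75 for Egr1, 3.08 for Fos and 1.83 for the immediate early list median (log2). For the tumour against the non-tumour region, the effect at 37 degrees lay above that at 6 degrees by 2.48 for the immediate early list median, 2.42 for Il1a, which encodes interleukin 1 alpha, and 1.13 for the hepatocyte list median. The difference of 37 minus 6 degrees was larger in the tumour region than in normal diet by 3.03 for Il1b and 2.94 for the hepatocyte list median, larger in the tumour than in the non-tumour region by 2.98 for Ccl4 and 2.44 for Plk2, and larger in normal diet than in the non-tumour region by 3.96 for Egr2. For the tumour region against normal diet, the effect at 37 degrees lay above that at 6 degrees by 3.23 for the retinol carrier Rbp4, 2.46 for Serpina1a and 2.70 for the hepatocyte list median, and for the non-tumour region against normal diet the hepatocyte list median did so by 1.5.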

How the results depend on the processing

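Alternatives that left out the tumour region library of 37 degrees, the endothelial and macrophage list genes or the genes higher at 6 degrees were chosen after seeing the data; the cause of a change was not tested unless named. For temperature, the 593 genes became 330 with a mean of at least 5 FPKM (fewer genes tested), 0 without the filter (1019 higher and 1820 lower unadjusted) and 0 without the source term (424 and 814), 82 to 475 with libraries left out (32 higher and 50 lower without the non-tumour pair), and 569 without endothelial and macrophage genes. The 18 list calls became 11 under quantile normalization, of which 10 were kept and 1, the oxidative phosphorylation list, was new. They became 10 without the source term and 0 with an estimated correlation. Fry, which compares a list with no other genes and so asks another question, gave 0 lists (smallest adjusted p 0.117). For the tumour region against normal diet, the 1082 genes became 505 without the filter, 681 with a mean of at least 5 FPKM, 657 with 4 libraries and 505 without the tumour region library of 37 degrees, and the 17 list calls 0 with an estimated correlation; fry gave 1 list (MHC class I, adjusted p 0.0251). Quantile normalization moved the split from 702 higher and 380 lower to 541 and 471. For the non-tumour region against normal diet, the 643 genes became 268 without the filter, and the 10 list calls 0 with an estimated correlation; fry gave 1 list (MHC class I, adjusted p 0.0218). For tumour against non-tumour region, the 52 genes became 0 with a pseudocount of 0.1 FPKM (722 higher and 418 lower unadjusted), without the filter (1153 and 501), with a mean of at least 5 FPKM (439 and 321), with 4 libraries (740 and 426), without the genes higher at 6 degrees (678 and 430) and without the tumour region library of 37 degrees (580 and 328), 1 with small RNA genes kept and 122 with robust empirical Bayes, and the 18 list calls 0 with an estimated correlation; fry gave 0 lists (smallest adjusted p 0.133). Directions reversed under quantile normalization for the ribosomal list with temperature (-0.0320), the ribosomal list in the tumour region against normal diet (-0.107) and H2-K1 in the same contrast (-0.0939). Spearman in place of Pearson gave 0.533, 0.510 and 0.278 for the effects of the 3 source contrasts at both temperatures. Genes at least 2-fold apart between 37 and 6 degrees, with no test, numbered 566, 691 and 723 in normal diet, non-tumour and tumour libraries and 358, 394 and 443 with a mean of at least 5 FPKM (fewer genes). The libraries of 37 or of 6 degrees alone leave no residual degrees of freedom, so they gave values and no test. Depth limits values near the 0.0443 to 0.0623 FPKM that 1 fragment on 1 kb is worth.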

Other observations

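The test of the clock genes and the choice of those genes came after their values were seen. With temperature, Bhlhe40 and Inhba rose among 13 TGF-beta response genes, so 2 passed, and 5 higher and 1 lower adjusted over the list alone. Inhba did not pass without any of the 3 pairs, and Bhlhe40 did not without the normal diet or the tumour pair. Camera gave the TGF-beta list adjusted p = 0.00859, adjusted p = 0.508 with an estimated correlation and 0.0542 without the normal diet pair. Rgs4, a regulator of G protein signalling, rose by 0.79 ± 0.13 as the 1 passing gene of 12 vascular smooth muscle genes, and 2 passed adjusted over the list alone. It did not pass without the non-tumour or the tumour pair (adjusted p = 0.21 and 0.0922). Camera gave the smooth muscle list adjusted p = 0.0327, adjusted p = 0.525 with an estimated correlation, 0.173 without the non-tumour pair and 0.0948 under quantile normalization. Lrat was the 1 passing gene of 16 retinoid and lipid droplet genes, and 2 passed adjusted over the list alone. Camera gave the retinoid list adjusted p = 0.0385, adjusted p = 0.508 with an estimated correlation, 0.0913 without the non-tumour pair, 0.246 without the tumour pair, 0.214 under quantile normalization and 0.154 with a mean of at least 5 FPKM. The interferon-stimulated list had a median of 0.15 with 0 of 21 genes passing by limma or adjusted over the list alone (3 higher unadjusted). Camera gave the interferon list adjusted p = 0.00788, adjusted p = 0.508 with an estimated correlation and 0.0721 under quantile normalization. The unfolded protein response list had a median of 0.10 with 0 of 19 passing by limma or adjusted over the list alone (1 higher and 1 lower unadjusted). Camera gave the unfolded protein response list adjusted p = 0.0375, adjusted p = 0.649 with an estimated correlation, 0.0913 without the non-tumour pair, 0.246 without the tumour pair and 0.624 under quantile normalization. The alpha globin gene Hba-a1 fell by 1.58 ± 0.25 (adjusted p = 0.0319), but did not pass without the normal diet or the non-tumour pair (adjusted p = 0.0663 and 0.0854) or with a pseudocount of 0.1 FPKM.

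In the tumour region against normal diet, Dnajb4, Hsp90aa1 and the mitochondrial chaperonin Hspe1 rose among 17 heat shock genes, so 3 passed, and 9 adjusted over the list alone. Camera gave the heat shock list adjusted p = 6.17e-04, and adjusted p = 0.351 with an estimated correlation. Hsp90aa1 and Hspe1 did not pass under quantile normalization (adjusted p = 0.0506 and 0.0605) and Dnajb4 and Hsp90aa1 did not with a pseudocount of 0.1 FPKM. Hsp90aa1 did not under median-ratio rescaling either (adjusted p = 0.0506), and Hspa1a had a log2 fold change of -0.35 (adjusted p = 0.72). The immediate early list had a median of 1.03, with 1 of 30 genes higher by limma and also adjusted over the list alone. Camera gave it adjusted p = 3.83e-05, and adjusted p = 0.625 with an estimated correlation. The retinoic acid-forming enzyme gene Aldh1a2 rose by 1.22 ± 0.19 and the retinol dehydrogenase gene Rdh10 by 1.09 ± 0.18, while Dgat2, which makes triglyceride, fell by 1.81 ± 0.17; the retinoid list did not pass. Camera gave the retinoid list adjusted p = 0.782. Wt1, a transcription factor of mesothelial and stellate precursors, fell by 1.71 ± 0.19 in the tumour region and by 1.79 ± 0.19 in the non-tumour region against the same normal diet libraries. Of 12 portal fibroblast genes Dpt and Ly6a rose in the tumour region, so 2 passed, and 3 adjusted over the list alone. Camera gave the portal fibroblast list adjusted p = 0.0256, and adjusted p = 0.351 with an estimated correlation. In the tumour against the non-tumour region, the collagen list had a median of 0.28 with 0 of 20 genes passing by limma (8 higher unadjusted) and 1 adjusted over the list alone. Its medians were 0.03 at 37 degrees and 0.40 at 6 degrees. Camera gave the matrix list adjusted p = 1.69e-05, and adjusted p = 0.418 with an estimated correlation. The other lists that passed camera there were ribosomal (median 0.14, adjusted p = 2.48e-06), NRF2 (0.19, adjusted p = 0.00311), inflammasome (0.25, adjusted p = 0.00337), portal fibroblast (0.55, adjusted p = 0.00361), heat shock (0.15, adjusted p = 0.0116), TGF-beta (0.25, adjusted p = 0.0204) and hepatocyte genes (0.33, adjusted p = 0.0465). With an estimated correlation their adjusted p were 0.426, 0.337, 0.418, 0.337, 0.337, 0.347 and 0.688. By limma 0 genes of these 7 lists passed, and 2 inflammasome genes and 1 portal fibroblast gene were higher adjusted over the list alone. At an unadjusted p under 0.05, 3, 4, 3, 4, 4, 1 and 0 were higher in the order given. The ribosomal list did not pass under quantile normalization (adjusted p = 0.122), nor the hepatocyte list with a mean of at least 5 FPKM (adjusted p = 0.0608) or under median-ratio rescaling (adjusted p = 0.065). Hepatocyte list medians had opposite signs here, 0.98 at 37 degrees and -0.15 at 6 degrees, and the inflammasome ones were 0.42 and 0.04.

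Dbp and Tef, output genes of the circadian clock, were lower in both regions of high-fat diet livers than in normal diet by limma (adjusted p = 0.0103 and 0.0211 in the tumour and 0.0104 and 0.0233 in the non-tumour region, against the same normal diet libraries). Per1, Per2, Per3, Arntl and Npas2 did not pass in either contrast (adjusted p from 0.0501 to 0.892), and Hlf was under the expression filter. Dbp was at 7.27 and 8.53 FPKM in normal diet at 37 and 6 degrees, and at 1.05, 2.36, 1.33 and 2.35 FPKM in the 4 high-fat diet libraries. The median of Dbp, Tef, Hlf, Per1, Per2 and Per3 was -0.80 (high-fat minus normal diet, log2) and that of Arntl and Npas2, which peak at another time of day, 0.41, a difference of -1.21. Since these genes were picked for their values, this difference is not a test of the pattern. A candidate explanation is that livers of the 2 diets were collected at different times of day, which would move the groups apart in this way. An effect of the diet on the clock would do so too, and the labels used here give no collection times, so these cannot be told apart.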
